A study of Mus musculus with 6 samples.

How the data were processed

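The data are poly-A RNA sequencing counts from 6 libraries of mouse pancreatic cancer cells, 3 of aKO (Pik3ca removed) and 3 of p-aKO (Pik3ca and Pccb removed). Cells were grown without treatment at 37 °C and 5% CO2 in medium with 10% serum, and libraries were sequenced as paired reads of 150 bases, per the labels' protocols. Per the submitters' processing notes, the authors used FastQC, Trim Galore, HISAT2, SAMtools and HTSeq, and the versions and the settings of each are not given in the sources used here. The deposited values are raw counts, 1 whole number per gene and library, for 55487 gene identifiers. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart and genes with near-identical copies are treated as uncertain. The files also hold 5 HTSeq summary classes, which were kept out of library sizes and tests. They took 18.0 ± 1.11% of all counted reads in aKO and 15.1 ± 0.0825% in p-aKO (SD, n = 3 each).

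Gene counts per library were 33370016 to 40706136. In these libraries 25569 genes had at least 1 count, and 15051 passed the filter of edgeR (filterByExpr with a minimum count of 10 and a minimum total of 15) and were tested. Libraries were scaled with TMM, with factors from 0.986 to 1.03, and p-aKO was tested against aKO with the edgeR quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) without covariates. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The biological coefficient of variation was 0.191. Levels are CPM, gene counts divided by the TMM-scaled library size and given per 1e6, with SD over 3 libraries. Folds are 2 to the power of the fitted log2 fold change. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, data.table (1.17.8) and, for transcript length and GC content, Biostrings 2.70.1. Positions come from GENCODE M21 on GRCm38, which holds 55141 of the 55487 identifiers and 15033 of the 15051 tested, and need not be the annotation used for the counting.

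Before the data were examined, 35 gene lists were fixed: propionate and branched-chain amino acid catabolism, MHC class I, MHC class II, interferon response, T cell checkpoint and costimulatory ligands, chemokines and cytokines, NF-kB, cholesterol synthesis and uptake, fatty acid and triglyceride synthesis, fatty acid oxidation, TCA cycle and anaplerosis, respiratory chain subunits, mitochondrially encoded mRNAs, glycolysis, hypoxia, integrated stress response, unfolded protein response, NRF2, PI3K-AKT, MAPK output, p53 targets, proliferation, epithelial, mesenchymal, classical and basal-like subtypes, collagens and matrix, DNA methylation and histone modifying enzymes, histones, ribosomal proteins, immune cells, endothelial cells, fibroblasts and pericytes, acinar and endocrine cells, and duct. The 32 lists with at least 5 tested members were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists tested. Camera with an estimated correlation and fry were run beside it. The genes named in the text follow a rule also fixed beforehand: Pccb, Pik3ca, Kras and Trp53; the 12 called genes with the largest rise and the 12 with the largest fall among those with a mean of at least 5 CPM and no overlap between the groups, without unnamed genes and pseudogenes; up to 4 called members of each list with a mean of at least 1 CPM; and, whether or not they passed, Cd274, B2m, H2-K1, H2-D1, Tap1, Nlrc5, Pcca, Mmut, Cxcl10, Ccl2, Ccl5 and Pik3cb.

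The test was run on simulated counts drawn from the means and sizes of these libraries. For p-aKO against aKO, with 14746 genes run, edgeR recovered 9 of 47 genes changed 1.5-fold (19.1%), 37 of 46 changed 2-fold (80.4%), 43 of 49 changed 4-fold (87.8%) and 48 of 48 changed 8-fold (100%), and 10 of 147 calls (6.80%) were false. Far fewer genes were changed in this simulation than were called in the data (54.8% of those tested). The adjustment over all genes was therefore stricter in it, and these shares need not hold for the data. Of 20 simulated lists of 25 genes, with 1 raised by 1 on the log2 scale, camera with the preset correlation, camera with an estimated correlation (adjusted p = 0.00977) and fry each called that list and no other. The simulated genes were drawn independently, so this run does not check the preset correlation for lists whose members vary together. In the data the estimated correlation of the proliferation list was 0.698. Among the called lists it ran from -0.0535 (classical subtype) to 0.872 (mitochondrially encoded mRNAs), and only that of the classical list was below the preset one. Its call was lost too, with camera p = 0.000167 for the preset and p = 0.0156 for the estimated correlation, both before adjustment. A call lost with an estimated correlation therefore need not mean that the members of a list vary together. The alternatives tried were RLE and upper-quartile scaling, library totals only, no filter, a filter of 10 CPM in 3 libraries, estimation without robustness, a test against a 1.5-fold change, mitochondrial genes left out, the DESeq2 Wald test, limma-voom, the replicate number as a covariate, each library left out in turn and an offset per chromosome.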

Results

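Poly-A RNA sequencing was compared between 2 lines of mouse pancreatic cancer cells. Both lines come from KPC cells, pancreatic tumor cells that carry Kras G12D and Trp53 R172H. The aKO line lacks Pik3ca, which encodes the alpha catalytic subunit of PI 3-kinase. The p-aKO line was made from aKO by also removing Pccb, which encodes the beta subunit of propionyl-CoA carboxylase, a mitochondrial enzyme in the breakdown of branched-chain amino acids and odd-chain fatty acids. Each line gave 3 untreated libraries, and no parental KPC library was analysed here, so all differences are those of p-aKO from aKO. Gene counts per library ranged from 33370016 to 40706136, with a mean of 35624100 ± 2604230 (SD, n = 3) in aKO and 38617600 ± 1808770 (SD, n = 3) in p-aKO. The labels do not say whether the 3 libraries of a line came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The first principal component held 78.3% of the variance and separated the lines. On it p-aKO replicate 2 stood at 58.6, the other p-aKO libraries at 86.5 and 84.8, and the aKO libraries between -82.6 and -73.3.

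The targeted genes were read first, because they check the labels. Pccb (ENSMUSG00000032527) was lower in every p-aKO library than in every aKO library: it was counted 754, 698 and 1108 times in aKO replicates 1 to 3, and 85, 120 and 48 times in p-aKO replicates 1 to 3. Its level was 23.8 ± 4.44 CPM (counts per 1e6 gene counts; SD, n = 3) in aKO and 2.17 ± 0.909 CPM (SD, n = 3) in p-aKO, which is 10.9-fold lower (log2 fold change -3.45, SE 0.30, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.06e-05). In the GENCODE M21 annotation of GRCm38, Pccb is a protein-coding gene on the minus strand of chromosome 9, from 100982032 to 101034898. Pik3ca (ENSMUSG00000027665), on the plus strand of chromosome 3 from 32397671 to 32468486 in the same annotation, was still counted in both lines, at 39.8 ± 1.18 CPM in aKO and 32.8 ± 2.21 CPM in p-aKO (SD, n = 3 each). Both lines share that deletion, no library with an intact gene was analysed here, and counts over a whole gene need not cover the deleted part, so these counts do not check the Pik3ca label. Its log2 fold change of -0.28 (SE 0.11) did not pass the edgeR test (adjusted p = 0.0597). It passed without p-aKO replicate 2 (log2 fold change -0.32, edgeR adjusted p = 0.0269), with upper-quartile scaling (-0.43, edgeR adjusted p = 0.0112) and with the stricter count filter (-0.36, edgeR adjusted p = 0.0194), and it was 0.19 (edgeR adjusted p = 0.181) when measured against the median of chromosome 3. Of the mutated driver genes, Trp53 rose 1.88-fold (log2 fold change 0.91, SE 0.14, edgeR adjusted p = 0.000489). Kras rose 1.30-fold (log2 fold change 0.38, SE 0.12, edgeR adjusted p = 0.0188), a call that was lost with upper-quartile scaling (0.22, edgeR adjusted p = 0.115) and without aKO replicate 1 (0.36), aKO replicate 2 (0.34), p-aKO replicate 1 (0.38) or p-aKO replicate 3 (0.31), with edgeR adjusted p from 0.0572 to 0.0905.

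**Figure D1:**
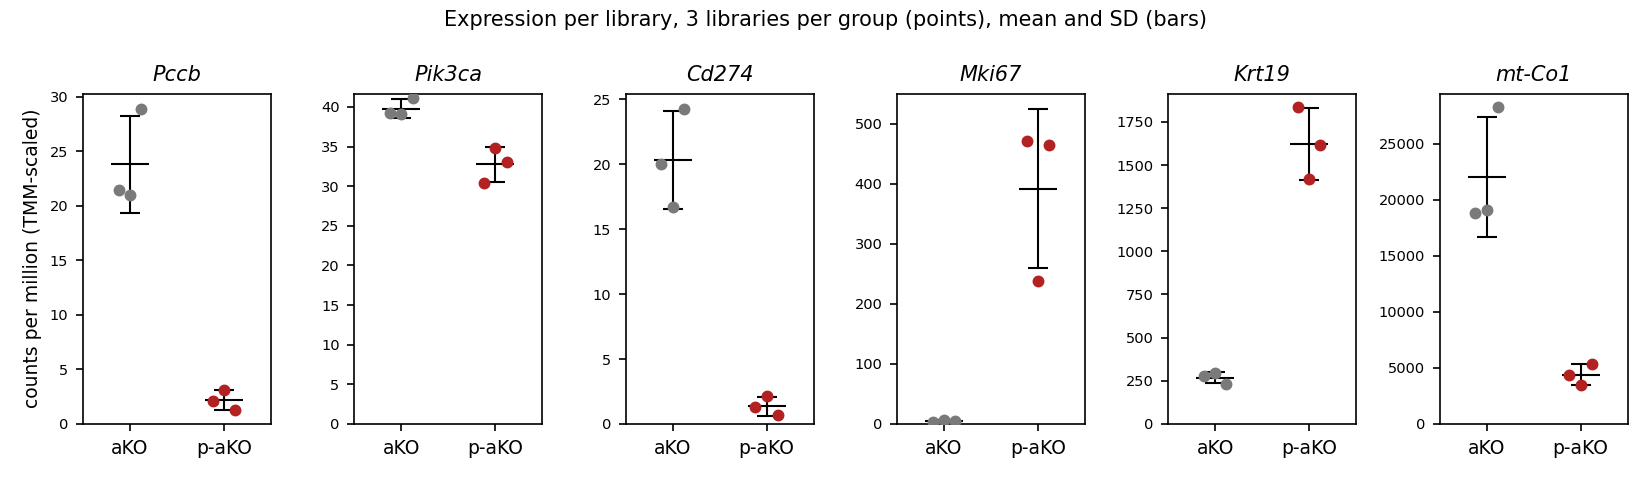
Expression of 6 genes in each library, in CPM on linear axes that start at 0. Points are libraries of aKO (grey) and p-aKO (red), with mean and SD as bars (n = 3 each). Pccb, Cd274 and mt-Co1 were lower and Mki67 and Krt19 higher in every p-aKO library than in every aKO library. Pik3ca was also lower in every p-aKO library, but did not pass the edgeR test.

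The comparison of p-aKO with aKO shows which transcripts differ between the 2 lines, each of which is 1 cell line, so effects of Pccb loss and other differences between the lines are not separated. Mki67, the gene of the proliferation antigen Ki-67, went from 5.05 ± 1.69 CPM in aKO to 392 ± 133 CPM in p-aKO (SD, n = 3 each), 77.6-fold higher. The other 11 genes that rose most were Shisa2, Cenpf, Aspm, Pcolce2, Kif14, Pif1, Tnxb, Phf19, Knl1, Myh14 and Klb, with log2 fold changes from 5.25 to 6.46. Cenpf, Aspm, Kif14 and Knl1 encode proteins of the kinetochore and mitotic spindle. Mgp, which encodes a secreted inhibitor of calcification, fell from 38.4 ± 5.77 to 0.122 ± 0.0839 CPM (SD, n = 3 each), 309-fold lower. The other 11 genes that fell most were Poglut1, Lcn2, Plcb4, Cacng7, Pdgfrb, Glipr2, Sirpa, Itgb8, Reck, Aldh1a1 and Bdh2, with log2 fold changes from -6.70 to -4.53. Of 15051 genes tested with edgeR, 8248 (54.8%) passed an adjusted p of 0.05, of which 4145 were higher and 4103 lower in p-aKO. With upper-quartile scaling the split was 3333 higher and 4995 lower. Of the called genes, 3950 differed by at least 1 on the log2 scale, 1840 of them higher and 2110 lower. For 9649 genes (64.1%, against 10% by chance) the 3 libraries of one line did not overlap those of the other. Single libraries moved some of these folds by over 1.5 times: without p-aKO replicate 2 the log2 fold change was -7.55 for Lcn2, -6.38 for Glipr2 and -6.26 for Itgb8, without p-aKO replicate 3 it was -8.91 for Mgp and -5.88 for Reck, and without aKO replicate 1 it was 5.90 for Klb.

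All 30 genes of the list for proliferation and cell cycle rose in p-aKO, and 30 passed when adjusted over the list alone. Their median log2 fold change was 3.91. Beside Mki67, the mitotic kinase gene Plk1 rose 35.5-fold (3.75 ± 0.992 to 133 ± 34.8 CPM), the kinesin gene Kif20a 30.4-fold (5.52 ± 0.496 to 168 ± 31.5 CPM) and the cyclin gene Ccna2 28.4-fold (6.64 ± 0.772 to 189 ± 47.2 CPM; SD, n = 3 each throughout). In p-aKO replicate 2 Mki67 stood at 239 CPM, against 472 and 464 CPM in the other p-aKO libraries and at most 6.98 CPM in aKO. Camera with the preset correlation, which compares a list with the other genes, gave adjusted p = 2.41e-17 for this list, and adjusted p = 0.600 with an estimated correlation. Over the 32 lists with at least 5 tested members, camera with the preset correlation called 10 (7 up and 3 down), camera with an estimated correlation 0 and fry 16. The loss of all 10 calls does not by itself show that members vary together, as the classical subtype list lost its call with an estimate below the preset correlation. Other splits of the same libraries into 3 and 3 gave 5 to 10 lists with the preset correlation. In each of them edgeR called 0 genes. Those splits still hold the lines unequally, so they are not free of the line difference and cannot decide whether the list calls mark it. The camera calls are read here only as how the members of a list moved in these libraries.

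Cd274, which encodes the checkpoint ligand PD-L1 and lies on the plus strand of chromosome 19 from 29367455 to 29388095 (GENCODE M21, GRCm38), fell 14.9-fold in p-aKO, from 20.3 ± 3.79 to 1.36 ± 0.716 CPM (SD, n = 3 each; log2 fold change -3.89, SE 0.35, edgeR adjusted p = 1.34e-05). Genes of the interferon response fell with it: of 37 tested, 22 were lower, 3 higher and 12 did not pass, with the same 22 and 3 adjusted over the list alone and a median log2 fold change of -1.28. Isg15, an interferon-induced ubiquitin-like modifier, fell 15.5-fold, its protease gene Usp18 13.8-fold and the guanylate-binding protein gene Gbp3 10.9-fold, while Isg20, Cmpk2 and Ifitm3 rose. Camera gave adjusted p = 0.000483 for the interferon list, and adjusted p = 0.669 with an estimated correlation. Without p-aKO replicate 2 the log2 fold change of Isg15 was -4.75 against -3.95 with all libraries. In the list of MHC class I antigen presentation 6 of 19 genes were lower, 0 higher and 13 did not pass (3 lower adjusted over the list alone; camera adjusted p = 0.301). B2m, the light chain of MHC class I, fell 1.78-fold, from 392 ± 28.5 to 220 ± 57.6 CPM (edgeR adjusted p = 0.00266). The heavy chain genes H2-K1 (log2 fold change 0.36, edgeR adjusted p = 0.0945) and H2-D1 (0.22, edgeR adjusted p = 0.250) and the peptide transporter gene Tap1 (-1.05, edgeR adjusted p = 0.175) did not pass. Nlrc5, a transactivator of MHC class I genes, had a log2 fold change of -2.73 (edgeR adjusted p = 0.0343) at 0.935 ± 0.343 CPM in aKO and 0.138 ± 0.217 CPM in p-aKO. That call was lost without aKO replicate 1 (-2.95), aKO replicate 2 (-2.78), aKO replicate 3 (-2.41), p-aKO replicate 1 (-2.24) or p-aKO replicate 3 (-2.17), and without p-aKO replicate 2 the value was -5.85.

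The lists for checkpoint ligands, chemokines and NF-kB did not pass camera, and their tested members went both ways. Of 17 genes for T cell checkpoint and costimulatory ligands, 7 were lower, 4 higher and 6 did not pass (7 and 5 adjusted over the list alone; camera adjusted p = 0.540). A further 12 listed ligand genes had at most 48 counts in any library and were not tested. Lgals3, the gene of galectin-3, rose 5.43-fold and the adhesion receptor gene Ceacam1 9.72-fold. Of 23 chemokine and cytokine genes, 6 were higher, 9 lower and 8 did not pass (6 and 9 adjusted over the list alone; camera adjusted p = 0.403). The monocyte chemokine gene Ccl2 rose to 1.76 ± 0.786 CPM from 0.123 ± 0.0913 CPM (log2 fold change 3.81, SE 0.66, edgeR adjusted p = 0.000794), Ccl9 rose 8.53-fold, and the cytokine gene Il11 fell 12.4-fold. Cxcl10 had a log2 fold change of -1.53 (edgeR adjusted p = 0.0354), which did not pass without aKO replicate 1 (-1.72), aKO replicate 2 (-1.58), aKO replicate 3 (-1.26), p-aKO replicate 1 (-1.28) or p-aKO replicate 3 (-1.37). Ccl5 had at most 6 counts in any library and was not tested. It was among 15 untested genes of the chemokine and cytokine list, none of which exceeded 15 counts in any library. Of 20 NF-kB targets and regulators, 5 were higher, 7 lower and 8 did not pass (5 and 8 adjusted over the list alone; camera adjusted p = 0.579). The adhesion gene Vcam1 fell 3.75-fold and the NF-kB regulator gene Nfkbiz 2.68-fold. In the list of MHC class II genes only H2-DMa and H2-DMb1 had enough counts for a test, too few for camera, and H2-DMb1 fell 10.4-fold. Of the immune cell markers only Cd68 was tested, at 3.41 ± 1.27 CPM in aKO and 1.95 ± 0.266 CPM in p-aKO (edgeR adjusted p = 0.0619), and none of the other 23 exceeded 20 counts in any library.

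Genes of lipid synthesis, glycolysis and the antioxidant response rose in p-aKO. Of 24 genes of cholesterol synthesis and uptake, 19 rose, 0 fell and 5 did not pass, with 19 and 0 adjusted over the list alone and a median log2 fold change of 0.80. The LDL receptor gene Ldlr rose 3.53-fold (96.3 ± 52.1 to 340 ± 60.5 CPM), Pcsk9, which lowers that receptor, 4.03-fold, and the sterol reductase gene Dhcr24 3.19-fold. Camera gave adjusted p = 0.000422 for cholesterol synthesis, and adjusted p = 0.733 with an estimated correlation. Of 19 genes of fatty acid and triglyceride synthesis, 12 rose, 1 fell and 6 did not pass (12 and 1 adjusted over the list alone; camera adjusted p = 0.00352, and adjusted p = 0.666 with an estimated correlation). Acaca, acetyl-CoA carboxylase, rose 3.37-fold, the desaturase gene Fads2 3.60-fold and the fatty acid synthase gene Fasn 2.93-fold (253 ± 61.9 to 741 ± 217 CPM). Of 21 glycolysis genes, 14 rose, 0 fell and 7 did not pass (14 and 0 adjusted over the list alone; camera adjusted p = 0.00277, and adjusted p = 0.669 with an estimated correlation). The pyruvate kinase gene Pkm rose 2.21-fold and the enolase gene Eno1 2.03-fold. Gapdh is uncertain, as its many processed pseudogenes may share its reads, which was not tested, and as 1 library stood apart. It stood at 16.0 ± 1.21 CPM in aKO and 68.4 ± 68.7 CPM in p-aKO, where replicate 3 alone held 147 CPM, and its log2 fold change went from 2.10 to 0.86 without that library. The Gapdh call was lost without aKO replicate 2 (2.09), aKO replicate 3 (2.04) or p-aKO replicate 2 (2.41). Of 23 NRF2 antioxidant genes, 16 rose, 2 fell and 5 did not pass (16 and 2 adjusted over the list alone; camera adjusted p = 0.00922, and adjusted p = 0.576 with an estimated correlation). Gclc, which encodes the limiting enzyme of glutathione synthesis, rose 3.58-fold and the transketolase gene Tkt 3.45-fold, while the heme oxygenase gene Hmox1 fell 2.69-fold.

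The list that holds Pccb did not pass camera. Of 27 genes of propionate and branched-chain amino acid catabolism, 11 fell, the deleted gene Pccb among them, 4 rose and 12 did not pass (11 and 5 adjusted over the list alone; camera adjusted p = 0.234). Aldh6a1, the methylmalonate semialdehyde dehydrogenase of valine breakdown, fell 3.17-fold (35.5 ± 5.23 to 11.2 ± 3.87 CPM) and the leucine pathway gene Mccc1 2.11-fold, while the cytosolic transaminase gene Bcat1 rose 3.52-fold. Pcca, the partner subunit of Pccb, stood at 29.3 ± 5.25 CPM in aKO and 30.8 ± 0.841 CPM in p-aKO (log2 fold change 0.07, edgeR adjusted p = 0.691), and Mmut, which acts 2 steps downstream, at 37.4 ± 5.68 and 38.2 ± 4.22 CPM (0.03, edgeR adjusted p = 0.861). Without aKO replicate 2 the value was -0.04 for Pcca and -0.07 for Mmut, and Mmut stood at -0.01 without p-aKO replicate 1 or p-aKO replicate 3. Of 27 TCA cycle genes, 14 rose, 4 fell and 9 did not pass (14 and 4 adjusted over the list alone; camera adjusted p = 0.121, and adjusted p = 0.0416 without p-aKO replicate 2). Citrate synthase, Cs, rose 1.95-fold and the dehydrogenase gene Mdh1 fell 2.02-fold. Of 23 genes of fatty acid oxidation, 8 fell, 2 rose and 13 did not pass (8 and 2 adjusted over the list alone; camera adjusted p = 0.220), with Hadh 1.54-fold and Eci2 1.55-fold lower. Measured against the median of its chromosome, Hadh stood at -0.15 and was not called, against -0.62 without that offset.

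Transcripts made from mitochondrial DNA were lower in p-aKO. Of 12 tested, 11 fell, 0 rose and 1, mt-Nd3, did not pass (11 and 0 adjusted over the list alone), with a median log2 fold change of -1.99. The cytochrome oxidase transcript mt-Co1 fell from 22050 ± 5368 to 4403 ± 960 CPM and mt-Nd4 from 3190 ± 929 to 531 ± 97.0 CPM (SD, n = 3 each). Camera gave adjusted p = 0.000238 for the list, and adjusted p = 0.669 with an estimated correlation. All mitochondrially encoded genes together took 4.57 ± 1.27% of gene counts in aKO and 0.996 ± 0.186% in p-aKO (SD, n = 3 each). Of 35 subunits of the respiratory chain made from nuclear genes, 11 rose, 12 fell and 12 did not pass (11 and 12 adjusted over the list alone; camera adjusted p = 0.679). Atp5b rose 1.84-fold and Ndufb5 fell 2.45-fold. Among 30 ribosomal protein mRNAs, 2 rose, 7 fell and 21 did not pass (2 and 5 adjusted over the list alone; camera adjusted p = 0.495). Rps7 fell 2.48-fold and Rps2 rose 2.18-fold, though processed pseudogenes may share reads with many genes of this family, which was not tested. Among 14 histone genes that serve as a check on poly-A selection, 6 fell, 1 rose and 7 did not pass (6 and 1 adjusted over the list alone; camera adjusted p = 0.263). H1f2 fell 4.66-fold, from 250 ± 83.7 to 53.7 ± 26.1 CPM, while all 30 proliferation genes rose.

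Genes of epithelial identity and of the classical subtype of pancreatic cancer rose in p-aKO. Of 19 epithelial genes, 14 rose, 2 fell and 3 did not pass (14 and 2 adjusted over the list alone; camera adjusted p = 0.000483, and adjusted p = 0.576 with an estimated correlation). Another 6 listed genes, Epcam, Cldn7 and Esrp1 among them, had at most 11 counts in any library and were not tested. The keratin genes Krt19 (268 ± 32.8 to 1624 ± 208 CPM) and Krt8 (326 ± 31.7 to 1774 ± 340 CPM; SD, n = 3 each) rose 6.05-fold and 5.45-fold, while Cldn4 and Rab25 fell. Of 16 classical subtype genes, 11 rose, 1 fell and 4 did not pass (12 and 1 adjusted over the list alone; camera adjusted p = 0.000892, and adjusted p = 0.501 with an estimated correlation). The estimated correlation of this list was -0.0535, lower than the preset one, so members that vary together do not account for its lost call. Another 7 listed genes, Tff1 and Reg4 among them, had at most 9 counts in any library and were not tested. Hnf4a, a transcription factor of gut and liver epithelium, rose 8.35-fold (19.7 ± 4.24 to 165 ± 32.1 CPM) and the cadherin gene Cdh17 13.4-fold. Of 7 fibroblast and pericyte markers with enough counts, 6 fell and 1 rose, with the same 6 and 1 adjusted over the list alone and a median log2 fold change of -3.08. The growth factor receptor gene Pdgfrb fell 49.7-fold (24.2 ± 4.63 to 0.483 ± 0.232 CPM) and Pdgfra 14.4-fold, Mylk rose, and Acta2 was 0 in every p-aKO library and at least 12.8-fold lower. With Acta2 at that bound the median stayed -3.08. Camera gave adjusted p = 0.0182 for the fibroblast list, and adjusted p = 0.576 with an estimated correlation. The camera call was lost without aKO replicate 2 (adjusted p = 0.0802), aKO replicate 3 (adjusted p = 0.0536) or p-aKO replicate 1 (adjusted p = 0.0753).

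The mesenchymal, collagen, basal-like, duct and endothelial lists did not pass camera. Of 19 mesenchymal genes, 2 rose, 8 fell and 9 did not pass (2 and 8 adjusted over the list alone; camera adjusted p = 0.121). Vim, the intermediate filament gene vimentin, rose 4.55-fold (937 ± 88.4 to 4261 ± 203 CPM), while Serpine1, a plasminogen activator inhibitor, fell 6.41-fold and the matrix gene Sparc 5.24-fold. Of 29 collagen and matrix genes, 13 rose, 12 fell and 4 did not pass (13 and 12 adjusted over the list alone; camera adjusted p = 0.832). Thbs1, thrombospondin 1, fell 11.7-fold (1591 ± 116 to 137 ± 20.1 CPM) and the laminin gene Lamb3 rose 9.61-fold. The median (-0.21) and mean (-0.01) of the collagen list were negative and its camera direction was up, and its median was 0.03 in 1 of the settings tried. Of 11 basal-like subtype genes, 4 rose, 3 fell and 4 did not pass (4 and 3 adjusted over the list alone; camera adjusted p = 0.293), with Anxa8 3.91-fold higher and Sprr1a 5.43-fold lower. Another 13 listed genes, Krt5, Krt14 and Krt17 among them, had at most 4 counts in any library and were not tested. Of 14 pancreatic duct markers, 5 rose, 3 fell and 6 did not pass (5 and 3 adjusted over the list alone; camera adjusted p = 0.631). Spp1, osteopontin, fell 8.46-fold and took 3.59 ± 0.0228% of gene counts in aKO as the most abundant gene there. Of 5 endothelial markers, 1 rose, 2 fell and 2 did not pass (1 and 2 adjusted over the list alone; camera adjusted p = 0.403), with Pecam1 4.72-fold lower at 1.73 ± 0.218 CPM in aKO. Of the acinar and endocrine markers only Cela1 was tested, too few for camera, and it fell 2.64-fold.

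Signalling, stress and chromatin lists did not pass camera either. Of 28 PI3K-AKT components, 11 rose, 6 fell and 11 did not pass (11 and 8 adjusted over the list alone; camera adjusted p = 0.462). Inpp4b, a phosphoinositide phosphatase, rose 19.1-fold (0.558 ± 0.106 to 10.8 ± 2.29 CPM), the regulatory subunit gene Pik3r3 fell 3.75-fold, and Pik3cb, the beta catalytic subunit, stood at 28.7 ± 1.40 and 31.6 ± 6.88 CPM (log2 fold change 0.14, edgeR adjusted p = 0.502). Without p-aKO replicate 2 Pik3cb passed at 0.31 (edgeR adjusted p = 0.0310). Of 17 genes of MAPK output, 6 rose, 7 fell and 4 did not pass (6 and 7 adjusted over the list alone; camera adjusted p = 0.579). The cyclin gene Ccnd1 rose 5.17-fold and the ERK phosphatase gene Dusp6 fell 3.28-fold. Of 21 p53 targets, 4 rose, 8 fell and 9 did not pass (4 and 9 adjusted over the list alone; camera adjusted p = 0.403). The antiproliferative gene Btg2 fell 17.6-fold (377 ± 33.6 to 21.5 ± 15.7 CPM), with a log2 fold change of -4.13, and of -4.92 without p-aKO replicate 2. Of 17 hypoxia genes, 5 rose, 10 fell and 2 did not pass (5 and 10 adjusted over the list alone; camera adjusted p = 0.325), with Bnip3 2.65-fold lower and Pdk1 2.59-fold higher. Of 28 genes of the integrated stress response and amino acid supply, 12 rose, 6 fell and 10 did not pass (12 and 6 adjusted over the list alone; camera adjusted p = 0.156). The amino acid transporter gene Slc7a5 rose 5.20-fold and Mthfd2 of mitochondrial folate metabolism 3.47-fold. Of 17 genes of the endoplasmic reticulum unfolded protein response, 2 rose, 3 fell and 12 did not pass (2 and 2 adjusted over the list alone; camera adjusted p = 0.851), and the co-chaperone gene Dnajb9 fell 6.13-fold. The median of this list was 0.00 and above 0, its mean -0.15 and its camera direction down, and its median ran from -0.16 to 0.02 over the settings tried. Of 31 DNA methylation and histone modifying enzymes, 13 rose, 5 fell and 13 did not pass (13 and 5 adjusted over the list alone; camera adjusted p = 0.206). Uhrf1, which recruits the maintenance methyltransferase to replicated DNA, rose 17.1-fold, and that methyltransferase, Dnmt1, rose 7.25-fold (72.9 ± 13.3 to 528 ± 162 CPM).

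**Figure D2:**
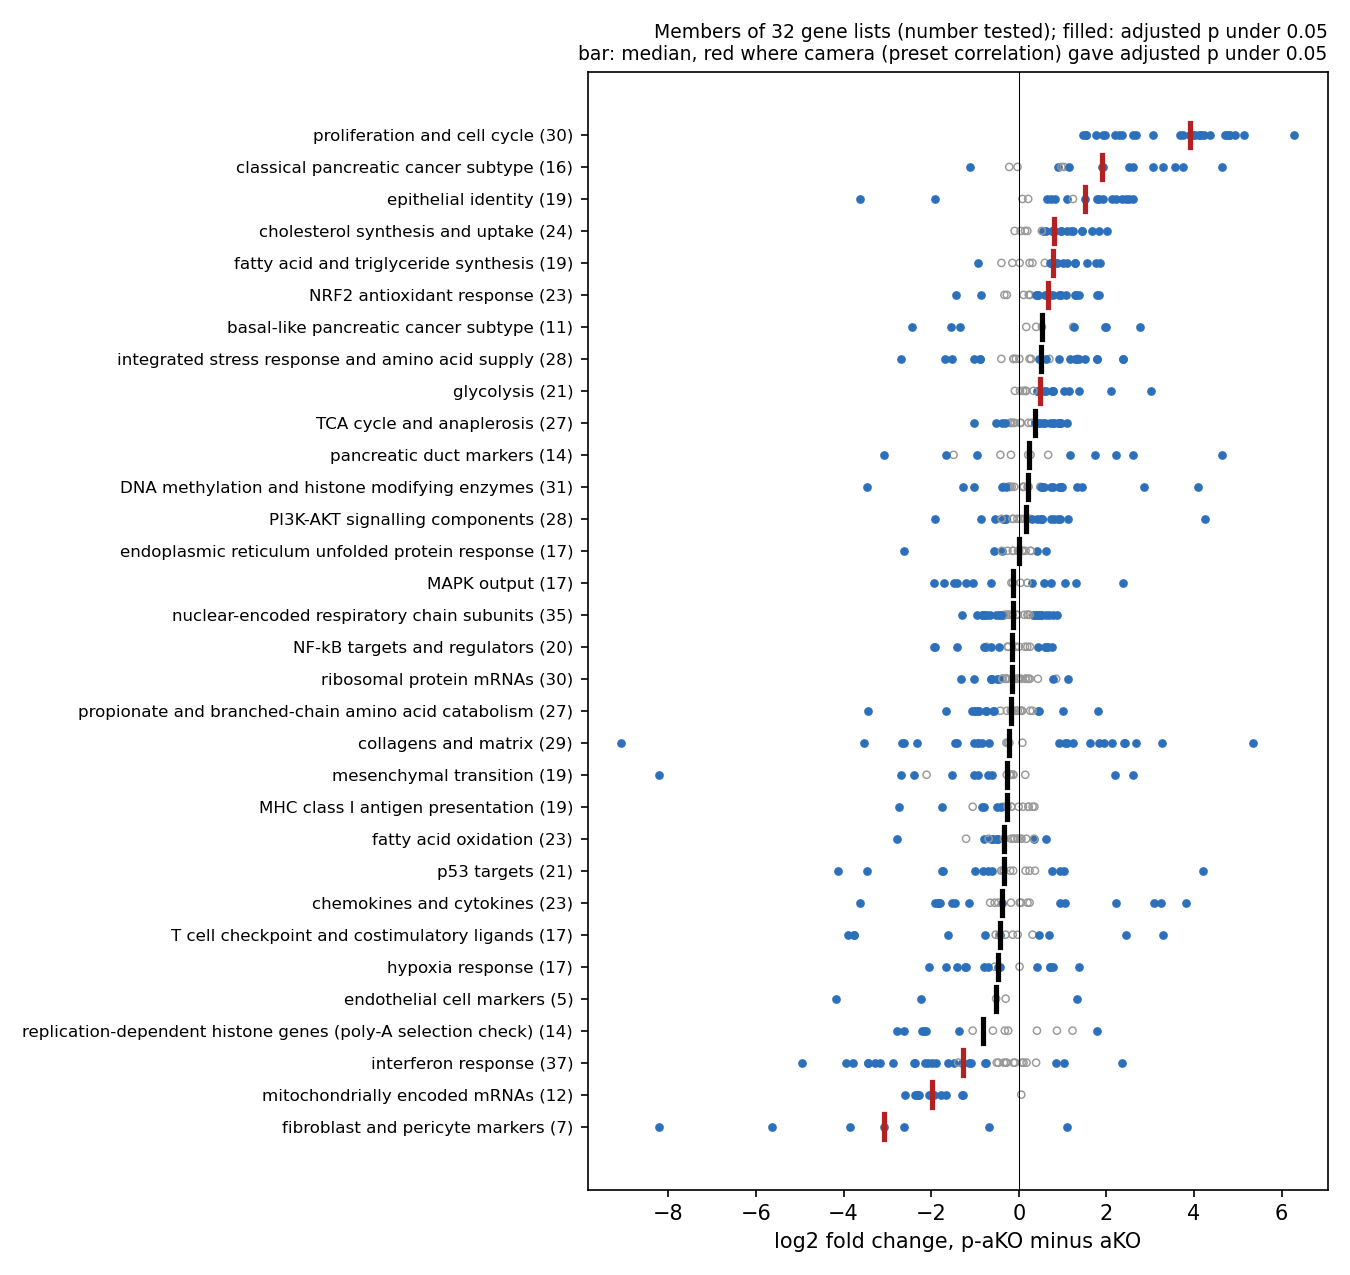
Log2 fold changes of p-aKO from aKO (horizontal axis) for the tested members of 32 gene lists, with the number of tested members behind each list's name. Filled points passed an edgeR adjusted p of 0.05, open points did not, and bars are list medians (3.91 for proliferation, -3.08 for fibroblasts), red for the 10 lists called by camera.

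Whole chromosomes were shifted as well. Over 10648 genes with a mean of at least 5 CPM on the autosomes and chromosome X of GENCODE M21, the median log2 fold change was 0.06. It was 0.53 for the 837 genes of chromosome 2, of which 76.1% lay above the median of all genes, -0.47 for the 531 genes of chromosome 3, of which 25.2% did, and -0.28 for the 366 genes of chromosome 12, of which 32.2% did. The differences from the median of all genes were 0.47, -0.54 and -0.35, and for the remaining 17 chromosomes they were at most 0.18 in size. Each of the 3 p-aKO libraries showed these shifts relative to the aKO mean, from 0.44 to 0.47 on chromosome 2, from -0.55 to -0.53 on chromosome 3 and from -0.36 to -0.31 on chromosome 12. A permutation test that drew genes at random gave the smallest p that 10000 draws can give, 1e-04 (two-sided), for chromosomes 2, 3, 6, 12 and 13, and 7 of 20 chromosomes passed after Benjamini-Hochberg adjustment. This test is across genes, which are not independent replicates.

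**Figure D3:**
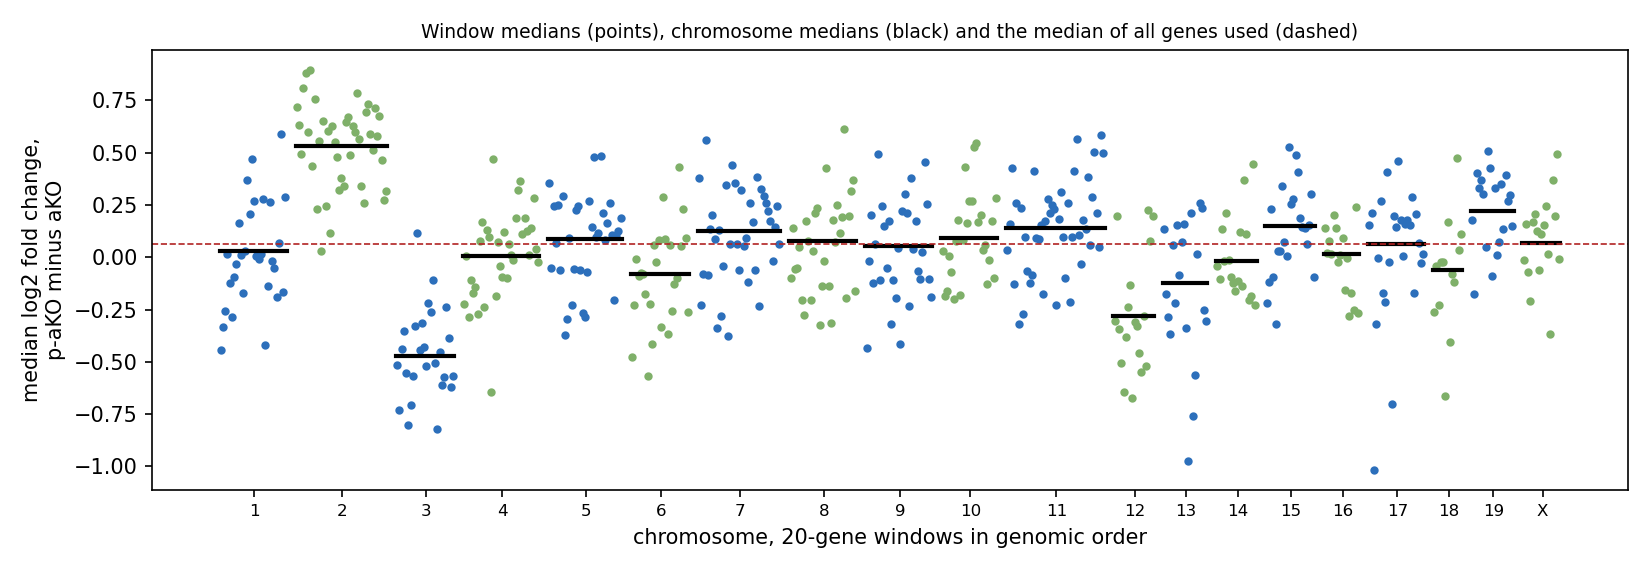
Median log2 fold change of p-aKO from aKO (vertical axis) in windows of 20 neighbouring genes (points), in genomic order along chromosomes 1 to 19 and X (horizontal axis, colours alternate by chromosome). Black lines are chromosome medians (0.53 for chromosome 2, -0.47 for chromosome 3 and -0.28 for chromosome 12) and the dashed line is the median of all 10648 genes.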

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

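The 2 results below come from the HTSeq summary classes, which lie outside the gene counts, and were picked out because every p-aKO library lay above every aKO library. Reads that HTSeq could not assign between overlapping genes were 4.78% of all counted reads in p-aKO (4.71 to 4.93%) and 4.42% in aKO (4.19 to 4.55%). Reads below its alignment quality were 0.951% in p-aKO (0.943 to 0.967%) and 0.732% in aKO (0.609 to 0.799%). Another class also separated all libraries, the other way: reads without a unique alignment were 4.28% in p-aKO (4.27 to 4.28%) and 7.87% in aKO (6.99 to 9.25%). None of these differences was tested.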

How the results depend on the processing

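The alternatives were chosen before the data were examined, except the chromosome offset and the further scalings of the lists, which were chosen after seeing the data. Of 86 alternative counts of genes and lists 80 stayed within 1.5 times, of 3070 alternative values for named genes 2969 kept their direction and side of the threshold, and of 447 for lists 427 did. The number of genes called was 8227 with RLE scaling, 8328 with upper-quartile scaling, 8175 with totals only, 8561 without a filter, 6223 with the strict filter, 8245 without robust estimation, 8232 without mitochondrial genes, 8449 with DESeq2 and 8436 with limma-voom. Upper-quartile scaling moved the median log2 fold change of all genes from -0.03 to -0.18. A test against a 1.5-fold change called 4050 genes, 2010 higher and 2040 lower, as its construction asks for larger changes. The strict filter left 2161 called genes with a log2 fold change of at least 1 in size, because fewer genes (9861) were tested. Pik3ca stood at -0.43 with upper-quartile scaling, -0.36 with the strict filter and 0.19 with the chromosome offset, which subtracts the chromosome 3 median. Leaving out 1 library at a time gave -0.32 to -0.23 for Pik3ca, -0.0362 to 0.22 for Pcca and -0.0703 to 0.15 for Mmut, and 6767 to 9173 called genes. Pcca turned to -0.0828 with upper-quartile scaling and -0.0126 with the strict filter, Mmut to -0.13, -0.0541 and, with the chromosome offset, -0.0286, and Pik3cb to -0.0224 with upper-quartile scaling; none of these passed edgeR, and the cause was not tested. Of the gene lists, camera with an estimated correlation called 0 and fry 16. The replicate block gave 7835 called genes and the same 10 lists, and Gapdh, Cxcl10 and Insr were not called under it. Libraries with the same number did not deviate together (correlations from -0.0569 to -0.00985, against -0.0170 to 0.0390 for other numbers), which gives no sign that the numbers pair them. With so few libraries per line only a strong shared effect could have shown. The chromosome offset gave 8117 calls. Among other named genes, it left Mccc1 at -0.60, Ndufb5 at -0.82, Pdk1 at 0.84, Vim at 1.65, Hnf4a at 2.53 and Nup188 at 1.64. Without the offset these stood at -1.08, -1.29, 1.37, 2.18, 3.06 and 2.17, and each stayed called. Part of each of these folds is thus shared with the chromosome of the gene. Folds of 1.5 were recovered in 19.1% of simulated genes. That simulation changed far fewer genes than were called in the data, so the share need not hold there.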

Other observations

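Gene families were formed after the data were seen, by the root of the gene symbol, with at least 10 tested members, and some share members with the fixed lists. Of 149 families camera called 11, 8 up and 3 down, and 0 with an estimated correlation (adjusted p = 0.861 for each). Whether members that vary together account for these lost calls was not tested. Of 17 tested protocadherin beta genes, a cluster on 1 chromosome, 15 fell and 0 rose (median log2 fold change -2.89, camera adjusted p = 9.70e-05), with Pcdhb14 at -4.80 and Pcdhb17 at -3.97. Of 20 nucleoporin genes 17 rose and 0 fell (median 0.90, camera adjusted p = 0.000166), with Nup188 at 2.17 and Nup210 at 1.97. Of 340 zinc finger genes named Zfp, 41 rose and 166 fell (median -0.50, camera adjusted p = 0.000166). Of 31 kinesin genes, 2 of them in the fixed lists, 24 rose and 4 fell (median 1.37, camera adjusted p = 1.50e-05). Of 18 genes named Rad, 12 rose and 1 fell (median 0.78, camera adjusted p = 0.00261), with Rad51, which pairs DNA strands in repair, at 3.83 and Rad51ap1 at 3.74.

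Of the called genes with a mean of at least 1 CPM in aKO, singled out after their values were seen, 15 had no count in any p-aKO library. The sulfotransferase gene Chst11 stood at 8.15 ± 1.59 CPM in aKO (SD, n = 3) and was at least 105-fold lower in p-aKO, and Asb4 at 5.38 ± 0.919 CPM and at least 69.3-fold lower, taking 3 counts per library as the floor. The transcription factor gene Myb stood at 2.02 ± 0.554 CPM in p-aKO and was at least 23.9-fold higher there, with no count in any aKO library.

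For the rise of the proliferation list, the scaling and FOXO tests were chosen after the result was seen, and scaling set by a few abundant genes does not explain it, since the lowest list median over 6 scalings and tests was 3.69. The lowest p-aKO library held 5.93 times the mean level of the list in the highest aKO library, which a different growth state of the cultures would also give, so growth state stays possible. Targets of FOXO factors could be active in an arrested aKO line: of 18 tested, 15 fell and 2 (Insr and Yod1) rose, with a median log2 fold change of -0.83 (camera p = 0.000446, and p = 0.187 with an estimated correlation), but the list was written after several members were seen, and the demand for the second p was added after the result, so this cannot be told. The calls of Insr and Yod1, the only members that rose, were both lost without aKO replicate 1 (0.36 for Insr and 0.45 for Yod1), aKO replicate 2 (0.28 and 0.44) or p-aKO replicate 1 (0.31 and 0.49), Insr also without aKO replicate 3 (0.28) and Yod1 without p-aKO replicate 3 (0.40). Members that fell with similar edgeR adjusted p, such as Irs2 (0.043), Klf6 (0.029) and Rbl2 (0.026), were not checked in this way. The lost calls of Insr and Yod1 therefore do not make the list more one-sided. Whether the loss of Pccb itself raised the proliferation genes remains open, because each genotype is 1 cell line and no second line was analysed here.

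For the chromosome shifts, all tests were chosen after the chromosome medians were seen, with their predictions written before the tests were run. A copy number difference between the lines may underlie them: 97.6% of windows of 20 genes on chromosome 2, 96.2% on chromosome 3 and 77.8% on chromosome 12 were shifted the chromosome's way, the last just under the 80% set beforehand, so this cannot be told without DNA data. Trends with GC content and transcript length do not explain the shifts of chromosomes 2 and 3, of which at least 90.8% was left after their removal, but 72.9% was left on chromosome 12, where a part in the shift stays open. Without genes changed by 1 or more on the log2 scale at least 62.0% was left. Leaving genes out by the same fold change whose median is measured can itself shrink a shift. This value therefore cannot decide whether a minority of strongly changed genes contributes. An effect of Pccb loss on these chromosomes was not tested.

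For the mitochondrially encoded mRNAs, the tests of non-unique reads and of scaling were chosen after the result was seen. The share of non-uniquely aligned reads differed by -3.59 percentage points, lower in p-aKO, which was the outcome set for no loss of reads at nuclear copies of mitochondrial DNA. That share covers all reads, so it cannot exclude such a loss. It was highest in aKO replicate 3 (9.25%), which also held the largest mitochondrial share of gene counts (6.04%). Scaling does not explain the fall of these mRNAs, with a highest list median of -1.97. A difference in RNA integrity may contribute, as the correlation of log2 fold change with transcript length was 0.175 across 10648 genes, between the 2 limits set beforehand. The correlation with GC content was 0.192 across the same genes, so the trend with length need not come from RNA integrity. A lower content of mitochondrial transcripts through the loss of Pccb remains open and was not tested.

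The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, as it is never below 0.1. The real split gave 8248 genes with edgeR, as did 1 of 10 splits counting itself, and the highest other gave 0 (at most 375 before adjustment). It gave 10 lists with camera, a number reached by 2 of 10 splits counting itself, and the highest other gave 10. The other splits still hold the lines unequally, so the number of lists cannot decide whether the list calls mark the line difference.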
